A study of Mus musculus with 10 samples.

How the data were processed

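RNA-seq was performed on myofibroblastic cancer-associated fibroblasts (myCAFs) that had been flow-sorted by surface CD90 from mouse pancreatic ductal adenocarcinomas. The tumours grew after orthotopic transplantation of KPC T-LOH organoids, per the labels. The markers used to define the myCAF gate other than CD90 are not given in the sources used here. There were 10 libraries, made from 5 tumour pools with a CD90-positive and a CD90-negative fraction each. The sample titles give both fractions of a pool the same animal numbers, so the pool number pairs the libraries. The titles name 11 animals over the 5 pools, whereas the design text counts 5 male mice. This difference could not be resolved, and n is given here as pools.

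Per the labels, libraries were prepared from total RNA with a low-input stranded kit, from 0.1 to 1.2 ng of RNA whose integrity (RIN) ran from 3.1 up to 8.7. Samples of low input received 10 cDNA PCR cycles and samples of higher input 5, followed by 14 final cycles. Neither the input nor the integrity number of a given library is recorded in the labels. Low input and PCR without molecular identifiers make reads non-independent, so counts overstate the number of molecules sampled.

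The authors deposited an estimated count per transcript for each library, from Salmon 1.9.0 per the submitters' processing notes, which name the builds GRCm39 and mm39. The annotation release, the strand setting and the bias options are not given in the sources used here. The deposited files also hold TPM and effective lengths. TPM values were not used in any test, and effective lengths entered only an alternative fit. No column of another sample was present.

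Transcript identifiers were matched without their version to the GENCODE M21 annotation of GRCm38, which was used only for gene names, biotypes and chromosomes. No coordinates are given because the builds differ. Of 144584 transcripts, 133666 (92.4%) matched. The 10918 others carried between 3.63% and 12.1% of the counts of a library, and 58.4% of those counts fell on 1 transcript. Estimated counts were summed per gene over 48471 genes and rounded to whole numbers. Totals ranged from 11.7 to 47.7 M per library (M, mega), of which 3.71 to 28.5 M fell on nuclear protein-coding genes. Reads of paralogs and pseudogenes were divided by Salmon's model, so values of near-identical genes such as Hspa1a and Hspa1b are uncertain.

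Differential expression was tested with edgeR 4.0.16 in R 4.3.3 (filterByExpr on the group, TMM normalization, glmQLFit with robust estimation, glmQLFTest), with the tumour pool as a block. Log2 folds are CD90-negative over CD90-positive, their standard errors follow from the F statistic, and p values were adjusted by Benjamini-Hochberg with a threshold of 0.05. CPM refer to the TMM-scaled library. Gene lists were tested with camera in limma 3.58.1 on log2 CPM (prior count of 2) with a preset correlation of 0.01 and again with an estimated one, and with fry. Adjustment was over all 29 lists (19 pathway or state lists and 10 cell type marker lists). Library-level measures were compared by an exact paired permutation test (sign flips over 5 pools, two-sided), whose smallest possible p is 0.062. No pair of libraries of the same group agreed within counting noise, with chi-square per degree of freedom from 39.2 to 1605 over genes with at least 20 reads. The deviations of the 2 libraries of a pool from their group means correlated by 0.06, 0.00, 0.46, 0.03 and 0.19 in pools 1 to 5, so the block rests on the shared animals and not on this check.

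The groups, the main fit, the gene lists, the rule for naming genes and most other settings were fixed before the data were examined. The rule named Thy1, the 12 largest folds in each direction (adjusted p under 0.05, mean log2 CPM of at least 3, same direction in all 5 pools, no Gm, Rik or pseudogene symbol), up to 4 members with the smallest p from a list that was called or held at least 3 called members, up to 2 from other lists, and every measured EGFR-family member. It gave 127 genes. Another 22 genes were chosen after their values were seen. Some further genes are also named after their values were seen, and all of these are marked as such. Values of some genes are not reported here. These other settings were no block, other size factors, DESeq2 1.42.0, limma-voom, other filters, a length offset, protein-coding genes only, each pool left out, and a threshold of 0.01. Settings added later left out mitochondrial genes, kept unmatched transcripts, added the mitochondrial rRNA share as a covariate, or left out pools 4 and 5.

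The pipeline was tested on simulated counts for this comparison, drawn for 15378 genes from the real means, dispersions and library sizes. Of these, 100 genes were changed 2-fold and 100 changed 4-fold. Each gene also received a log2 pool effect with an SD of 0.3, shared by both fractions of a pool. Whether real pool effects are of this size was not tested, so the recovery of the blocked fit may differ in the real libraries. Of the simulated genes, 14627 passed the filter. The edgeR fit with the pool as a block recovered 18 of 100 genes changed 2-fold and 69 of 100 changed 4-fold, with 6 false calls among 98 and no wrong direction. DESeq2 recovered 42 and 89 with 67 false calls among 205, and limma-voom 22 and 67 with 5 false calls among 101. A list of 11 genes lowered 2-fold was called at an adjusted p of 6.72e-11 by camera, with 0 of the others among 29 lists called. Genes were drawn independently of each other, so the simulation does not test list p values where members vary together. In the real libraries the estimated correlation within a list reached 0.82. Tables were computed with Python 3.11.15, pandas 2.3.3 and scipy 1.17.1, and figures with matplotlib 3.10.9.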

Results

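The transcriptomes of CD90-negative and CD90-positive myCAFs were compared within 5 tumour pools, to find how fibroblasts sorted by this surface protein differ in mouse pancreatic cancer. Cancer-associated fibroblasts are the matrix-producing cells of the tumour stroma, and the myofibroblastic kind carries contractile and matrix genes. The host strain was C57BL/6J. Pools 1 to 5 held 4, 1, 2, 3 and 1 animals by their titles. Each fraction had 5 libraries. The CD90-negative libraries held 33.3, 35.3, 38.0, 47.7 and 38.5 M estimated counts in pools 1 to 5, and the CD90-positive libraries 16.6, 29.8, 38.2, 28.5 and 11.7 M.

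Mitochondrial RNA took a larger share of the counts in CD90-negative libraries in 5 of 5 pools. Mitochondrially encoded genes made up 62.9% ± 18.0 of gene-assigned counts in the CD90-negative and 29.9% ± 14.0 in the CD90-positive fraction (SD, n = 5), with an exact paired permutation p of 0.062, the smallest that 5 pools allow, and an adjusted p of 0.125 over 4 measures. Nearly all of this was mitochondrial rRNA, at 59.3% ± 17.6 against 26.9% ± 12.8 (SD, n = 5), and it reached 84.4% in the CD90-negative library of pool 4. The 100 most abundant genes took 73.3% ± 14.1 against 53.2% ± 11.3 of the counts (SD, n = 5; exact p = 0.062, adjusted p = 0.125). Total counts averaged 38.6 ± 5.53 M against 24.97 ± 10.7 M (SD, n = 5; exact p = 0.125, adjusted p = 0.167), whereas counts on nuclear protein-coding genes averaged 11.1 ± 5.77 M against 15.2 ± 9.07 M and were lower in 3 of 5 pools (SD, n = 5; exact p = 0.25). In the CD90-negative and CD90-positive fractions 19173 ± 1911 against 19152 ± 2517 genes were detected (SD, n = 5; exact p = 1). CD90-negative library 4 had the fewest counts on nuclear protein-coding genes, at 3.71 M, against 4.57 M in CD90-positive library 5. CD90-positive library 5 had the lowest total count and stood apart on the second principal component, which held 22.7% of the variance. On the first, which held 32.3%, CD90-negative library 3 lay at 28.6, on the side of the CD90-positive libraries (9.77 to 91.8) and above CD90-positive library 5, and the other CD90-negative libraries lay between -118.7 and -56.9.

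**Figure D1:**
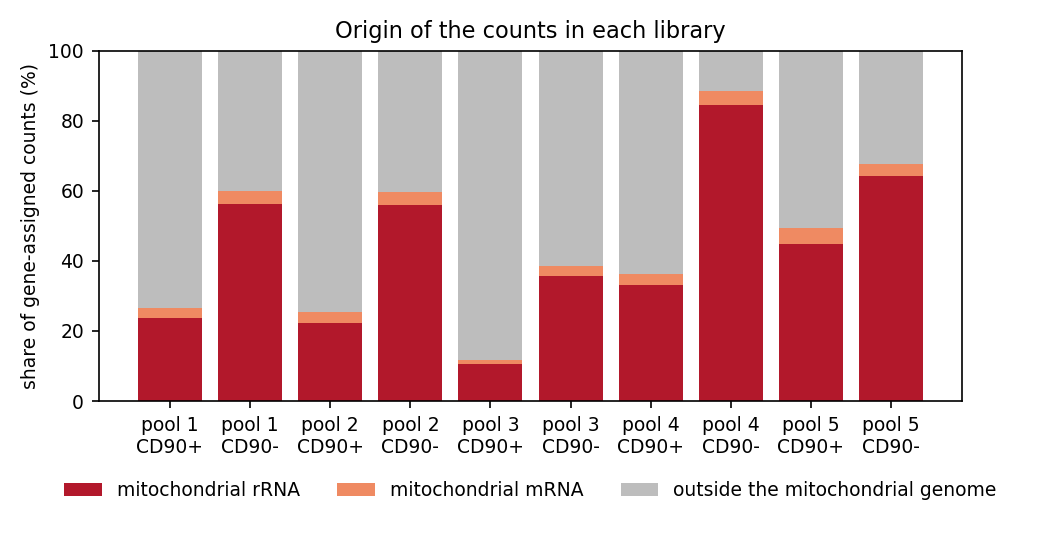
Share of gene-assigned counts (%) from mitochondrial rRNA, mitochondrial mRNA and outside the mitochondrial genome, stacked for each of the 10 libraries by pool and fraction. Mitochondrial rRNA was higher in the CD90-negative library of each of the 5 pools and reached 84.4% in pool 4.

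CD90-negative cells differed widely from CD90-positive cells of the same pools. Many of the tested fibroblast matrix, contractile and developmental signalling genes were lower, and many of the tested epithelial genes were higher. Of 15378 genes tested, 1980 (12.9%) changed: 896 were higher and 1084 lower in the CD90-negative fraction, and 615 and 826 of these by at least 2-fold. Most moved the same way in all 5 pools, with 870 of the higher and 1053 of the lower genes doing so. Thy1 (ENSMUSG00000032011, chromosome 9), which encodes CD90 and so checks the sort, was 11.3-fold lower, at 8.47 ± 5.18 against 89.1 ± 29.5 CPM (SD, n = 5), with a log2 fold of -3.50 (SE 0.50, adjusted p = 0.0056), and lower in 5 of 5 pools. Without the block for the pool, 965 genes were called (421 higher, 544 lower). The count fell to 675 without pool 1, 1252 without pool 2, 1239 without pool 4 and 541 without pools 4 and 5 (357 higher, 184 lower), and the edgeR fit with the mitochondrial rRNA share as a covariate called 0 genes, with 1813 at an unadjusted p under 0.05.

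Among genes with a mean log2 CPM of at least 3, the 12 largest increases included genes known from epithelia, such as Cldn18 and Cdh17. The lincRNA AC102496.1 was highest among them, with a log2 fold of 3.52 (SE 0.26, adjusted p = 0.00032). Cldn18, a tight-junction protein of gastric epithelium, averaged 90.4 ± 20.1 against 15.3 ± 13.2 CPM (SD, n = 5; log2 fold 3.01, SE 0.44, adjusted p = 0.0056). Tns4, a focal adhesion protein, rose by a log2 fold of 3.12, Lama3, a chain of the epithelial laminin 332, by 3.07, and Cdh17, an intestinal cadherin, by 2.98. Glp1r, the receptor for an incretin hormone, rose by 2.94, Tm4sf4 by 2.92, Wfdc2 by 2.88 and Ivl, a component of the cornified envelope, by 2.87. Glrp1, Dock8 and Arhgef28 completed the 12, at 3.28, 3.08 and 2.88. All 12 were higher in 5 of 5 pools, as the naming rule required, with adjusted p values up to 0.0221. With the mitochondrial rRNA share as a covariate the log2 fold of Lama3 turned to -0.035, not called. Lama3 and Wfdc2 lost their calls without the block for the pool, Dock8 without pool 1 or 5, Ivl without pool 1, 2 or 4, and Dock8 and Ivl without pools 4 and 5.

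The 12 largest decreases at the same abundance limit included contractile and matrix genes, such as Actg2 and Thbs2. Besides Thy1, they were Actg2, a smooth muscle actin (log2 fold -3.49, SE 0.40), the chemokine Cxcl14 (-3.39, SE 0.41), the fibrillin Fbn2 (-3.20, SE 0.37), Hs6st2 (-3.19), Itm2a (-3.12), the matricellular gene Thbs2 (-3.11, SE 0.25), the collagen gene Col8a1 (-3.07), the protease inhibitor Serpine2 (-3.01), the Wnt inhibitor Nkd2 (-2.96), Spon1 (-2.94) and Tagln, an actin-binding protein of contractile cells (-2.93). Spon1 averaged 53.6 ± 26.4 CPM in the CD90-negative and 405 ± 151 CPM in the CD90-positive fraction, and Thbs2 38.0 ± 12.0 against 329 ± 96.1 CPM (SD, n = 5). All were lower in 5 of 5 pools, as the naming rule required, with adjusted p values of at most 0.0057. Hs6st2 lost its call without pools 4 and 5.

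**Figure D2:**
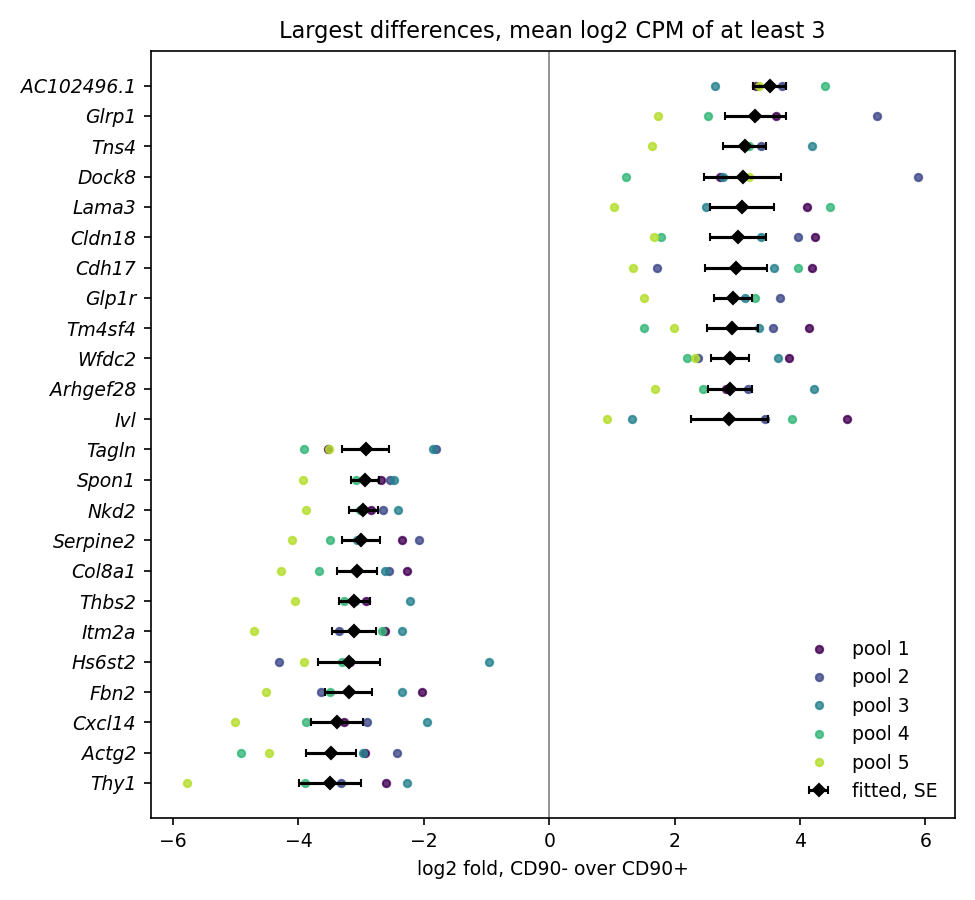
Log2 fold of CD90-negative over CD90-positive cells for Thy1 and the genes with the largest changes in each direction at a mean log2 CPM of at least 3; dots are the 5 pools, diamonds the fitted value and bars its SE. Every pool lies on the same side of 0 for every gene shown, from Thy1 at -3.50 to AC102496.1 at 3.52. The rule that chose the largest changes required this agreement of the 5 pools.

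Genes of the interstitial matrix and of the myofibroblastic state were lower in the CD90-negative fraction nearly throughout. Of 23 interstitial matrix genes, 22 fell and 0 rose (23 lower when adjusted over the list alone), with a median log2 fold of -2.23. The fibrillar collagen Col11a1 had a log2 fold of -2.90 (SE 0.19, adjusted p = 0.00022), Col5a1 of -2.16 (SE 0.29, 822 ± 408 against 3345 ± 546 CPM; SD, n = 5), Col6a2 of -1.96 and Col6a1 of -1.72. Of 19 myofibroblastic CAF genes, 17 fell and 0 rose (18 lower adjusted over the list alone), with a median of -2.58. Besides Thbs2 and Col8a1, these included Myl9, a myosin light chain (-2.83, SE 0.36), and the tropomyosin Tpm2 (-1.27, SE 0.14). Camera gave adjusted p values of 2.7e-15 for the matrix list and 1.5e-13 for the myofibroblastic list. Both had an adjusted p = 0.364 with an estimated correlation. The matrix median by pool was -2.40, -2.51, -0.73, -1.99 and -3.33 in pools 1 to 5. Without pools 4 and 5, 8 matrix and 13 myofibroblastic genes were still called lower. In the same libraries the median of the cancer epithelial markers was higher by 3.85, 0.66, 2.93, 2.31 and 1.17, and the mitochondrial rRNA share was higher in 5 of 5 pools.

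Most of the tested basement membrane and protease genes and some TGF-beta genes were also lower. Of 14 basement membrane genes, 9 fell and 3 rose (11 and 3 adjusted over the list alone); Col15a1 had a log2 fold of -2.85 (SE 0.35), Nid1 of -1.78, Col4a2 of -1.65 and Col4a1 of -1.50. The 3 that rose were Lama5 (1.70), Col18a1 (1.25) and Agrn (1.09), named here after their values were seen. Of 18 matrix proteases and inhibitors, 12 fell and 1 rose (13 and 1 adjusted over the list alone). The gelatinase Mmp2 fell by 2.48 on the log2 scale, Adamts2 by 2.28, Mmp14 by 1.26 and Plat by 1.04, while Mmp13 rose (1.88; named after its values were seen). Of 17 TGF-beta genes, 8 fell and 2 rose (10 and 2 adjusted over the list alone). Those that fell included Ltbp2 (-2.85), the ligand Tgfb3 (-1.78), Tgfbi (-1.45) and the receptor Tgfbr2 (-1.44). Ltbp1 (1.53) and Tgif1 (0.80), named after their values were seen, were the 2 that rose. Camera adjusted p values were 0.0014, 8.8e-06 and 0.0013 for these 3 lists, and each had an adjusted p = 0.364 with an estimated correlation. Cancer epithelial markers had a median log2 fold of 2.34 in these libraries, and the mitochondrial rRNA share was higher in 5 of 5 pools. Without pool 1, 5 basement membrane, 7 protease and 4 TGF-beta genes were called lower, without pool 2 5 TGF-beta genes, without the block for the pool 5, 4 and 4, and without pools 4 and 5, 4, 5 and 3. Of the genes that rose, 1 basement membrane, 0 protease and 1 TGF-beta gene were called without the block; 0 protease genes were called higher without pool 2 or without pools 4 and 5, and 1 TGF-beta gene without pool 1 or 2, without pools 4 and 5 or with a transcript length offset.

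Most of the tested Hedgehog and Wnt pathway genes were also lower. Of 10 Hedgehog genes, 7 fell and 0 rose (8 lower adjusted over the list alone; median -1.88), including the transcription factors Gli1 (-3.45, SE 0.56), Gli2 (-3.01, SE 0.59) and Gli3 (-1.95, SE 0.38) and the co-receptor Gas1 (-1.54, SE 0.23). Of 12 Wnt genes, 7 fell and 0 rose (9 lower adjusted over the list alone; median -1.82). The secreted Wnt antagonist Sfrp1 averaged 81.0 ± 10.95 against 485 ± 112 CPM (SD, n = 5; log2 fold -2.56, SE 0.17, adjusted p = 0.00022), and Dkk3 (-2.34), the receptor Fzd1 (-2.14) and Wnt4 (-1.80) followed. Camera adjusted p values were 8.8e-06 and 2.2e-05, and each list had an adjusted p = 0.364 with an estimated correlation. Without pool 1, 3 genes of each list were called lower, without the block 4 Hedgehog genes, and without pools 4 and 5, 1 Hedgehog and 2 Wnt genes. Among genes with a mean log2 CPM of at least 3, 4 Hedgehog genes were called. Cancer epithelial markers had a median log2 fold of 2.34 in the same libraries, and the mitochondrial rRNA share was higher in 5 of 5 pools.

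Some inflammatory genes of fibroblasts fell too, in libraries where the cancer epithelial markers had a median log2 fold of 2.34 and the mitochondrial rRNA share was higher in 5 of 5 pools. Of 19 inflammatory CAF genes, 8 fell and 0 rose (12 lower and 1 higher adjusted over the list alone; median -1.43). These included Svep1 (-2.07, SE 0.17), Pi16 (-1.89, SE 0.38), the chemokine Cxcl12 (-1.48, SE 0.25) and the interleukin-1 receptor Il1r1 (-1.30, SE 0.28). Of 20 cytokine and NF-kB genes, 4 fell and 0 rose (6 and 1 adjusted over the list alone): Csf1 (-1.86), Il6 (-1.83), Vcam1 (-1.40) and Cxcl1 (-1.10). Of 15 interferon response genes, 1 fell and 0 rose (5 lower adjusted over the list alone), while Gbp2 (-1.29), Isg15 (-1.76) and Bst2 (-1.60) had adjusted p values of 0.0588, 0.0657 and 0.0715. Of 14 immediate early and heat shock genes, 5 fell and 0 rose (10 lower adjusted over the list alone), with Hspa1a at -1.28, Jun at -0.94, Hspa1b at -0.86, Zfp36 at -0.76 and Ier2, named after its values were seen, at -0.51. Camera adjusted p values were 3.3e-05, 0.0195, 0.0011 and 0.00073 in this order, each with an adjusted p = 0.364 with an estimated correlation. The cytokine list was at 0.133 without pool 5, 0.212 without pools 4 and 5 and 0.0585 without the block, and the interferon list at 0.140 over genes with a mean log2 CPM of at least 3. Without pool 1, 3 inflammatory CAF, 1 cytokine, 0 interferon and 0 immediate early genes were called lower by edgeR. In this order the numbers were 5, 2, 0 and 1 without pool 2, 11, 6, 3 and 8 without pool 3, 6, 2, 0 and 3 without pool 4, and 6, 5, 0 and 2 without pool 5. They were 2, 0, 0 and 1 both without the block and without pools 4 and 5. The interferon list had a fry adjusted p of 0.0613, where fry tests whether the genes of a list move one way on balance and does not compare them with other genes. DESeq2 and limma-voom called 7 and 5 interferon genes and 9 and 10 immediate early genes lower with all pools, and edgeR with no filter on low counts called 13 inflammatory CAF, 7 cytokine and 6 interferon genes lower.

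EGFR-family ligands and receptors went in both directions. Of 12 measured members, 4 rose and 2 fell (the same numbers adjusted over the list alone). Among the ligands, Btc averaged 19.0 ± 6.55 against 3.16 ± 2.45 CPM (SD, n = 5; log2 fold 2.95, SE 0.52, adjusted p = 0.0085), Areg had a log2 fold of 2.81 (SE 0.38, adjusted p = 0.0038) and Hbegf of 1.31 (SE 0.24, adjusted p = 0.0084). The receptor Erbb2 rose by 0.86 (SE 0.17, adjusted p = 0.0111). The ligand Nrg1 was lower, at 0.276 ± 0.377 against 4.47 ± 1.17 CPM (SD, n = 5; log2 fold -4.96, SE 1.10, adjusted p = 0.0169), and Egfr was lower by a log2 fold of -0.64 (SE 0.18, adjusted p = 0.0452). Erbb3 (2.23), Tgfa (0.74), Ereg (-0.43), Adam17 (0.36), Egf (-0.60) and Errfi1 (0.04) did not pass, with adjusted p values from 0.172 to 0.903. Camera gave an adjusted p of 0.192 and fry of 0.0461. In these libraries the cancer epithelial markers had a median log2 fold of 2.34 and the mitochondrial rRNA share was higher in 5 of 5 pools. Without pools 4 and 5, 2 members were called higher and 0 lower, and without the block 1 and 1; without pool 4, 0 were lower. The call of Egfr was also lost without the block, without pool 1, 2 or 5 and with relative log expression size factors, upper-quartile normalization or a transcript length offset.

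Of 17 MAPK output genes, 5 rose and 1 fell (6 and 1 adjusted over the list alone; camera adjusted p = 0.160, fry adjusted p = 0.0331), beside the same median of 2.34 for the cancer epithelial markers and the higher mitochondrial rRNA share in 5 of 5 pools. The G1 cyclin Ccnd1 rose by a log2 fold of 2.35 (SE 0.37), the phosphatase Dusp5 by 1.20 (SE 0.17) and Fosl1 by 0.74 (SE 0.18), with Dusp6 (0.69) and Phlda1 (0.66) named after their values were seen, and Spry1 fell by 0.83 on the log2 scale. Without pool 1 or pool 5, 2 MAPK genes were called higher, without pool 3, 3, without pools 4 and 5, 2, and without the block 1. Spry1 was not called without the block, without pool 1 or 4, without pools 4 and 5 or with a transcript length offset. Of 11 YAP target genes, 5 fell and 2 rose (6 and 3 adjusted over the list alone; camera adjusted p = 0.0969, fry adjusted p = 0.0392), with Tgfb2 at -1.63, Lats2 at -0.94, Ccn1 at -0.92 and Arhgef17 at -0.77. The 2 that rose were Ankrd1 (1.38) and Crim1 (0.50), named after their values were seen; without the block, 0 YAP targets were called higher and 2 lower, without pool 1, 0 and 1, without pool 2, 0 and 4, without pool 3, 1 and 7, without pool 4, 1 and 3, without pools 4 and 5, 1 and 0, and with a transcript length offset 1 and 3. With no filter on low counts, or with unmatched transcripts kept, 1 was called higher. Of 15 mitosis genes, 0 passed in edgeR, with Bub1 at 4.63 (adjusted p = 0.0622) and Kif11 at 0.74 (adjusted p = 0.104), and 2 with an unadjusted p under 0.05; DESeq2 called 1, limma-voom 0 and edgeR with no filter on low counts 1. Of 13 DNA replication genes, 2 rose, Mcm7 (0.78) and Mcm6 (0.67), and 3 adjusted over the list alone, of which at most 1 was called when any pool was left out, 0 without the block, without pools 4 and 5 or with a transcript length offset, and 1 with unmatched transcripts kept. Of 16 hypoxia and glycolysis genes, 1 rose, Ndrg1 (0.70, adjusted p = 0.0156), and also 1 adjusted over the list alone, also called without pool 2 or pool 3 but not without the block, without pool 1, 4 or 5, without pools 4 and 5 or with a transcript length offset, whereas Pgk1 had a log2 fold of 0.57 (adjusted p = 0.155). Camera adjusted p values were 0.733, 0.192 and 0.764 for these 3 lists. Without pool 4 the hypoxia list had 0 genes called higher and 1 lower, and limma-voom and edgeR with no filter called 2 higher. With the mitochondrial rRNA share as a covariate they were 0.0410 and 0.0075, both towards higher, and 0.00011 towards lower, with 0 genes called in each list.

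MHC class II genes were few and low. Of 8 measured, the invariant chain Cd74 rose (log2 fold 1.20, adjusted p = 0.0286) and H2-DMb1 fell (-2.99, adjusted p = 0.0499), also when adjusted over the list alone; the camera adjusted p was 0.509. Without pool 1, 4 or 5, without pools 4 and 5 or with a transcript length offset, edgeR called 0 of them. H2-DMb1 was also not called without the block, without pool 2, with limma-voom, with mitochondrial genes left out or with unmatched transcripts kept, where Cd74 was, and DESeq2 called 2 genes higher and 1 lower. Of 13 mitochondrially encoded mRNAs, 3 rose and 0 fell (5 higher adjusted over the list alone): mt-Co1 (1.78, SE 0.42), mt-Atp8 (1.72, SE 0.30) and mt-Co3 (1.49, SE 0.30), while mt-Nd1 had a log2 fold of 1.21 (adjusted p = 0.0796). Without pool 1, 1 of them was called higher, without pool 5, 8, and without the block 0, with DESeq2 calling 10, limma-voom 2 and edgeR with no filter on low counts 12. Camera gave an adjusted p of 0.00015 and an adjusted p = 0.364 with an estimated correlation, and the fry adjusted p was 0.0561. With the mitochondrial rRNA share as a covariate the list turned to lower (camera adjusted p = 0.00054), mt-Co1, mt-Atp8 and mt-Co3 had log2 folds of -1.28, -0.49 and -0.18, and 0 of the 13 were called.

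Most of the tested markers of cancer epithelium were higher in CD90-negative libraries, and most were also present in CD90-positive ones. Of 16 cancer epithelial markers, 9 rose and 0 fell (13 higher adjusted over the list alone; median log2 fold 2.34). The keratins Krt18 and Krt8 averaged 570 ± 238 and 557 ± 230 CPM in the CD90-negative against 158 ± 111 and 207 ± 123 CPM in the CD90-positive fraction (SD, n = 5; log2 folds 2.04 and 1.48). Muc1, an apical mucin, had a log2 fold of 2.62 (SE 0.34) and the protease inhibitor Spint2 of 2.15 (SE 0.22). Epcam, named after its values were seen, averaged 53.6 ± 55.3 against 23.4 ± 40.7 CPM (SD, n = 5; adjusted p = 0.342), with log2 ratios of 6.27, -1.24, 2.91, 5.98 and 0.57 in pools 1 to 5. Without the block for the pool, 2 of the 16 markers were called, and DESeq2 called 14 and edgeR with no filter on low counts 15. The mitochondrial rRNA share was higher in the same libraries in 5 of 5 pools. Of 14 mesothelial markers, 4 rose and 1 fell (4 and 3 adjusted over the list alone): Krt18, Krt8, Krt19 (1.39) and Msln (1.40) rose, of which the 3 keratins are also on the cancer epithelial list, and Rspo1 (-1.30), named after its values were seen, fell. Their median log2 fold was -1.26, their mean -0.62 and the camera adjusted p 0.260; without the block 0 were higher and 1 lower. DESeq2 called 4 higher and 8 lower, edgeR with no filter on low counts 4 and 10 of 15, and limma-voom 4 and 1. Without pool 3, 3 were lower, without pool 1 or 2 or without pools 4 and 5, 0, and among genes with a mean log2 CPM of at least 3, 2. With the mitochondrial rRNA share as a covariate the list was lower (camera adjusted p = 0.00049) with 0 genes called. Of 4 acinar markers measured, Ctrb1 rose (3.63, adjusted p = 0.0380) and Cela2a had a log2 fold of 2.92 (adjusted p = 0.177). The camera adjusted p of the acinar list was 0.0885, but 0.0077 without pool 2, and the fry adjusted p was 0.0353; edgeR called 0 acinar markers without the block (adjusted p = 0.396 for the log2 fold of Ctrb1), without pool 1, 2, 3 or 4 or without pools 4 and 5. Limma-voom called 2, and edgeR with no filter 4 of 13.

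Some endothelial and macrophage markers rose, and 4 of 8 smooth muscle markers and 1 of 9 pericyte markers fell. Of 12 endothelial markers, 4 rose and 0 fell (6 higher and 2 lower adjusted over the list alone): the endothelial cadherin Cdh5 (4.86, SE 1.07), Tie1 (4.75, SE 1.04), Pecam1 (2.52, SE 0.64) and Flt1 (1.65, SE 0.36). Cdh5 had a log2 ratio of 9.94 in pool 2, and without that pool 1 endothelial marker was called higher and 1 lower; 1 was higher without pool 1, 2 without pool 3 or 4 and 0 without pools 4 and 5. DESeq2 called 6 higher and 2 lower, limma-voom 6 and 1 and edgeR with no filter 7 and 2; 1 was also lower without pool 3, with upper-quartile normalization, a transcript length offset, protein-coding genes only or mitochondrial genes left out. With the mitochondrial rRNA share as a covariate the log2 fold of Flt1 turned to -0.029, not called. Of 10 macrophage markers, Mrc1 (2.61) and Itgam (2.68) rose and 0 fell (3 higher adjusted over the list alone; 1 was called without pool 1, 2 or 4, without pools 4 and 5, without the block or with a transcript length offset, and 5 by DESeq2 and by limma-voom), and C1qa and C1qc, at 1.87 ± 1.10 and 2.01 ± 2.28 CPM in the CD90-negative against 0.398 ± 0.263 and 0.447 ± 0.510 CPM in the CD90-positive fraction (SD, n = 5), did not pass (adjusted p = 0.0855 and 0.144). Of 9 pericyte markers, Des fell (-2.48, adjusted p = 0.0089; 6 lower and 1 higher adjusted over the list alone), and Ndufa4l2 (-2.24), Cspg4 (-2.18) and Kcnj8 (-1.90) had adjusted p values from 0.0587 to 0.0825. Rgs5 (3.14, adjusted p = 0.111) and Mcam (0.84, adjusted p = 0.433), named after their values were seen, lay on the other side of 0, and 3 pericyte markers were called lower without pool 2, 3 or 5. DESeq2 called 1 pericyte marker higher and 7 lower, limma-voom 1 and 4, edgeR with no filter 1 and 5 and without the block 1 and 1; 2 were lower with upper-quartile normalization, protein-coding genes only or a mean log2 CPM of at least 3. Of 8 smooth muscle markers, 4 fell and 0 rose (5 lower adjusted over the list alone): Actg2, Cnn1 (-3.39), Mylk (-1.56) and Smtn (-1.14), with 7 called by DESeq2 and with no filter. Camera adjusted p values were 0.0064, 0.00074, 0.0118 and 6.3e-05 for the endothelial, macrophage, pericyte and smooth muscle lists and 3.2e-08 for the cancer epithelial list, each with an adjusted p = 0.364 with an estimated correlation. The endothelial and pericyte lists had fry adjusted p values of 0.0613 and 0.0547. Over the 3 endothelial markers with a mean log2 CPM of at least 3 the list turned to lower (camera adjusted p = 0.655), with a median log2 fold of -0.70, 1 higher and 1 lower. With the mitochondrial rRNA share as a covariate the endothelial, macrophage and cancer epithelial lists had camera adjusted p values of 0.142, 0.723 and 0.211. Neutrophil (Csf3r 0.57, Cxcr2 0.42), lymphocyte (Cd3d 0.27, Cd79a 0.45) and Schwann cell markers (Mbp 0.54) had 0 calls among 2, 2 and 5 tested, with unadjusted list p values of 0.470, 0.708 and 0.173; among these 3 lists 0, 0 and 2 genes had an unadjusted p under 0.05, DESeq2 called 0 and limma-voom 2, both Schwann cell markers, of which edgeR called 1 with no filter and 1 without pool 2, and the Schwann cell list had a fry adjusted p of 0.0331.

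Transcripts that differ between the sexes differed between the fractions, in mice that the design text describes as male. These genes were chosen after their values were seen. The Y-linked genes Ddx3y (log2 fold -1.71, adjusted p = 0.0136), Eif2s3y (-2.14, adjusted p = 0.0440), Kdm5d (-1.53, adjusted p = 0.0273) and Uty (-1.55, adjusted p = 0.0395) were lower in the CD90-negative fraction, by -2.04, -2.17, -0.40, -1.71 and -2.16 for their summed counts in pools 1 to 5. These summed counts stood at 63.5 CPM in CD90-negative library 3, within the 31.3 to 83.5 CPM of the CD90-positive libraries, and between 7.02 and 18.6 CPM in the other CD90-negative libraries. Without the block, without pool 1 or without pools 4 and 5, 0 of these 4 genes were called. Xist, the RNA that coats the inactive X chromosome, averaged 942 ± 522 CPM in the CD90-negative and 253 ± 269 CPM in the CD90-positive fraction (SD, n = 5; log2 fold 2.56, SE 0.68, adjusted p = 0.0550). It was higher in 5 of 5 pools, with log2 ratios of 4.13, 3.57, 3.42, 0.25 and 1.15. Xist stood at 383 and 666 CPM in CD90-positive libraries 4 and 5, and between 39.5 and 125 CPM in the other CD90-positive libraries. The CD90-negative libraries ran from 424 CPM in library 3 and 455 CPM in library 4 up to 1484 CPM in library 2. Over the other settings the adjusted p for the log2 fold of Xist lay between 6.3e-29 (no filter on low counts) and 0.450. The lowest value came from the same Xist counts as the planned fit and is not read as stronger evidence.

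**Figure D3:**
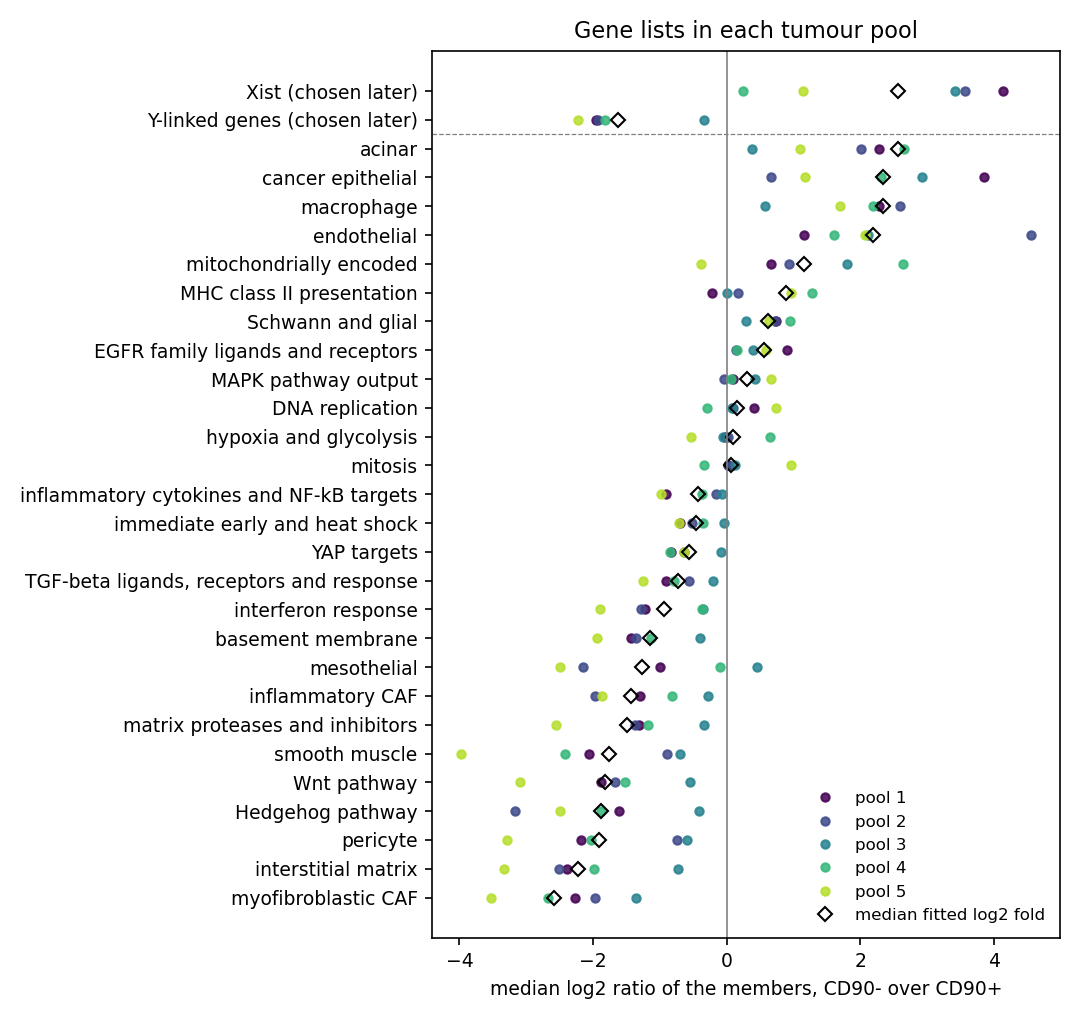
Median log2 ratio of the members of each gene list with at least 4 tested genes, CD90-negative over CD90-positive, for the 5 pools (dots) with the median fitted log2 fold (diamonds); the Y-linked genes and Xist at the top were chosen after their values were seen. Matrix and myofibroblastic lists lie below 0 in every pool, with pool 3 nearest to 0 at -0.73 and -1.35, and the cancer epithelial list lies above 0 in every pool.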

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

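Over 374 sets of 5 libraries (library measures, list means and named genes, per fraction), 31 held a library whose gap to the nearest other exceeded Dixon's 95% critical value for 5 samples, where chance gives about 18.7. Most fell on CD90-positive library 3, lowest for 8 and highest for 2, and CD90-positive library 5, lowest for 5 and highest for 1. Values below are log2 CPM of the library that stood apart.

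CD90-positive library 3 was the lowest of its group for the mean of the myofibroblastic CAF list (5.60), the mean of the immediate early and heat shock list (7.64), Thy1 (5.29), Cxcl14 (5.82), Nkd2 (4.42), Spon1 (7.22), Ltbp2 (6.93) and Hspa1b (7.38), and the highest for Egfr (7.43) and Bub1 (1.23). CD90-positive library 5, with the lowest total count, was the lowest for Csf1 (5.66), Ddx3y (3.46), Kdm5d (1.96), Eda2r (-0.41) and Trp53inp1 (1.22) and the highest for Erbb2 (5.42). CD90-positive library 2 was the highest for Ndrg1 (7.35) and Kcnj8 (4.16), and CD90-positive library 4 for Foxa2 (2.89).

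Among CD90-negative libraries, library 2 was the highest for the mean of the endothelial list (4.33) and for Cdh5 (5.96). Library 3 was the lowest for Hbegf (5.93), Btc (3.07) and Hnf4a (4.96) and the highest for Wnt4 (7.10). Library 5 was the lowest for the mean of the myofibroblastic CAF list (3.34), Gli1 (-2.87) and Kcnj8 (-1.48) and the highest for the mean of the Schwann and glial list (2.16). Library 1 was the highest for Fbn2 (6.61) and library 4 for mt-Nd1 (13.96).

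Transcripts with no gene match carried up to 12.1% of the counts of a library, in CD90-positive library 5, and entered a comparison between genes only in the setting that kept them.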

How the results depend on the processing

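The settings that left out mitochondrial genes, kept unmatched transcripts, added the mitochondrial rRNA share or left out pools 4 and 5 were chosen after seeing the data. Against 1980 genes changed (896 higher, 1084 lower), 308 higher and 396 lower passed at the 0.01 threshold, and 965 (421 and 544) without the replicate block, 3452 (1638 and 1814) with DESeq2, 3003 (1465 higher) with limma-voom, 541 (357 and 184) without pools 4 and 5, and 0, with 0 higher and 0 lower, with the mitochondrial rRNA share in the edgeR model, where 1813 genes had an unadjusted p under 0.05. Leaving out each pool gave 675 to 2019 genes, 308 to 820 higher and 367 to 1199 lower, the lowest without pool 1; fewer libraries entered these fits. The cause of the other shifts was not tested. Of the 127 genes named by the rule and the 22 chosen later, 53 lost their call without the block and 52 without pools 4 and 5. When a pool was left out, 10 to 47 lost it (47 without pool 1). With a transcript length offset 15 did, and at most 4 in other settings without the share. Genes named beyond these were not counted. No gene called both in an alternative and in the planned fit changed direction, and 930 of the 965 genes called without the block were shared with it. The Thy1 difference ran from -3.83 to -3.03 when a pool was left out, and was -4.94 with an adjusted p of 0.384 with the share as a covariate, against 3.0e-50 to 0.0227 in the other settings. The median log2 fold of all genes was 0.16 with the share and 0.036 without it. With that covariate the log2 fold of Lama3 (-0.035), mt-Atp8 (-0.49), mt-Co3 (-0.18), mt-Co1 (-1.28) and the log2 fold of Flt1 (-0.029) turned sign with none called, and the hypoxia (adjusted p = 0.00011) and mitochondrially encoded (adjusted p = 0.00054) lists turned to lower. The endothelial list turned at a mean log2 CPM of at least 3 (adjusted p = 0.655). Without the block no list call turned, and the NF-kB list lost its call (adjusted p = 0.0585). It also lost it without pool 5 (0.133) and without pools 4 and 5 (0.212), and the interferon list at a mean log2 CPM of at least 3 (0.140). With the share as a covariate the cancer epithelial (0.211), macrophage (0.723) and endothelial (0.142) lists lost theirs, while mitosis (0.0410), DNA replication (0.0075) and mesothelial (0.00049) lists gained one. Calls were also gained by the EGFR list (DESeq2, 0.0478), YAP targets (limma-voom, 0.0084; no filter, 0.0366; without pool 3, 0.0485) and the acinar list (no filter, 3.8e-05; length offset, 0.0330; without pool 2, 0.0077), all adjusted p. With an estimated correlation 0 of the 17 lists called by camera kept an adjusted p under 0.05. Fry called 18 of 29, but not the interferon (fry adjusted p = 0.0613), endothelial (0.0613), mitochondrially encoded (0.0561) and pericyte (0.0547) lists that camera called; it alone called the EGFR (0.0461), YAP (0.0392), acinar (0.0353), MAPK (0.0331) and Schwann cell (0.0331) lists. When a pool was left out, or with 10 reads for detection or the 50 most abundant genes, the differences in totals, genes detected and both shares moved by less than their SD over pools; that in genes detected took either sign. In simulation, 18 of 100 changes of 2-fold were recovered, so small changes at this depth can be missed.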

Other observations

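The tests against Y-linked counts, with the mitochondrial rRNA share as a covariate, of the sex of the hosts, of organoid cells and of mitochondrial RNA kinds were chosen after the results were seen, as were the genes of the next paragraph; the test of organoid cells was first run on those transcription factors (lowest pool median 1.07) then on the sign of the median of the markers fixed beforehand, which had been seen, and last on the difference between Xist and those markers. Scaling to collagen and the regrouping of libraries were set before their results were seen.

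Transcription factors of the pancreatic and foregut epithelium were higher in the CD90-negative fraction. Of 7 measured, 6 rose, among them Pdx1 (log2 fold 2.10), Foxa2 (2.44), Hnf4a (2.62), Ehf (2.23) and Onecut2 (2.52, at 368 ± 178 against 117 ± 147 CPM; SD, n = 5), while Foxa3 (4.49) had an adjusted p of 0.0621. Pdx1, Hnf4a, Ehf and Onecut2 were not called without the block for the pool or without pool 1. Of 10 target genes of p53, 4 fell and 0 rose, namely Ccng1 (-0.85), Zmat3 (-0.84), Phlda3 (-0.77) and Aen (-0.71), of which 0 were called without pool 1, without pool 4 or without pools 4 and 5. Mdm2 (-0.61, adjusted p = 0.0532), Cdkn1a (-0.50), Bax (-0.17), Sesn2 (-1.07), Eda2r (-1.88) and Trp53inp1 (0.50) did not pass. Cancer epithelial markers had a median log2 fold of 2.34 in the same libraries, and the mitochondrial rRNA share was higher in 5 of 5 pools.

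Of 100 splits of the 10 libraries into 5 and 5 (126 are possible), 1, the real one, called as many as 1980 genes, and the highest of the others called 332. That count came from the splits that put both libraries of pool 3 on one side and both of pool 4 on the other: since the fit compares libraries within pools, they hold the real contrast on pools 1, 2 and 5 and are no regrouping of it. Of the 16 splits that part every pool, the real one called 1980 genes and the highest of the others 0; 16 splits are too few for a share under 0.05.

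The lower level of matrix and myofibroblast genes could come from RNA of other cells or from a different state of CD90-negative fibroblasts, which stays open since the collagens used for scaling may themselves differ between states. When libraries were scaled to the summed counts of Col1a1, Col1a2 and Col3a1, 1 of the 39 other members, Cxcl14, was lower and 2 were higher. Dilution of 1 unchanged fibroblast population by any other cells predicts at most 1 lower member. The test cannot decide, because members that vary together with these collagens give few calls under either cause. The median log2 fold was 0.06, but members ran from -1.315 (Lrrc15, not called) to 1.47 (Fbln2). Over all genes 11005 were higher and 23 lower on that scale, the latter including Thy1 (-1.30), Itga11 (-1.48), Ptn (-1.60) and Nrg1 (-3.18). Lrrc15, Fbln2, Itga11 and Ptn are named here after their values were seen. Dilution only by cells that lack Y-linked transcripts is argued against as the whole cause for the matrix genes, since their median fell beyond the Y-linked counts in 5 of 5 pools, by a mean log2 ratio of -0.50 ± 0.38 (SD, n = 5; exact permutation p = 0.062, the smallest possible), and by -0.33 ± 0.036 (SD, n = 4) without pool 5, where the difference was -1.17 and the CD90-positive library was the lowest of its group for Ddx3y and Kdm5d. For the myofibroblast genes it cannot be told apart from other causes, because their median fell beyond the Y-linked counts in 4 of 5 pools, by -0.66 ± 0.63 (SD, n = 5, exact permutation p = 0.125). Both comparisons assume that Y-linked transcripts are equally abundant in host cells of both fractions, which was not tested. RNA quality, read from the mitochondrial rRNA share, cannot be told apart from the fraction, because the share follows it: with the share as a covariate the median of 42 members went from -2.23 (median SE 0.36) to -3.25 (median SE 1.04), all 42 stayed lower and the calls ended as the variance of the group term grew 9.89-fold.

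Xist was higher and Y-linked transcripts lower in CD90-negative libraries of animals described as male. Hosts of both sexes within a pool are argued against as the whole cause. The pools of 1 animal by their titles, 2 and 5, had Y-linked log2 ratios of -2.17 and -2.16 and Xist log2 ratios of 3.57 and 1.15. These pools do not bear on hosts of both sexes in the pools of more animals. The number of animals in the titles differs from that in the design text. RNA from cells of the transplanted organoids, if these derive from a female donor, which the labels do not state, cannot be told apart from other sources. The Xist log2 ratio and the median of the cancer epithelial markers were above 0 in all 5 pools but did not move together. Xist lay above the markers by 2.90 in pool 2 (3.57 against 0.66) and at -2.07 relative to them in pool 4 (0.25 against 2.31). In pool 4 Xist stood at 455 CPM in the CD90-negative and 383 CPM in the CD90-positive library. For the 7 epithelial transcription factors the medians were 3.27, 3.36, 3.69, 1.29 and 1.07 in pools 1 to 5. The Xist log2 ratios were 4.13, 3.57, 3.42, 0.25 and 1.15, so both were lowest in pools 4 and 5. These factors were chosen after their values were seen, so this cannot decide between sources. Of these 16 markers, 14 also averaged at least 1 CPM in CD90-positive libraries. The most abundant, Krt18, reached 570 CPM in the CD90-negative fraction, and 3 keratins are also on the mesothelial list. Besides these 3 and Msln (1.40), members of that list had log2 folds from -2.04 (Upk3b) to -0.98 (Cldn15). Upk3b and Cldn15 are named after their values were seen, and of these lower members only Rspo1 was called. More mesothelial RNA in CD90-negative libraries would raise these members too. They argue against it as the source of the keratin rise, while Msln goes the other way. Epcam had a log2 ratio of -1.24 in pool 2. A gate that excludes epithelial cells, if used, would remove such cells. The rise of Areg, Btc and Ccnd1 could have the same source and was not separated from a rise within fibroblasts.

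The mitochondrial rRNA share was higher in CD90-negative libraries in 5 of 5 pools. More mitochondrial RNA of all kinds is argued against as the whole cause, since rRNA rose beyond mitochondrial mRNA in 5 of 5 pools, by a mean log2 ratio of 0.82 ± 0.29 (SD, n = 5; exact permutation p = 0.062, the smallest possible), although mitochondrial mRNA was itself higher by 1.504 ± 0.96 relative to counts outside the mitochondrial genome. RNA quality or input of the sorted cells cannot be told apart from the fraction, as the labels give the RNA integrity of 0 of the 10 libraries. A difference in cell type between the fractions stays open.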
